A study of Mus musculus with 6 samples.

How the data were processed

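Whole liver RNA of male C57BL/6 mice, extracted with Trizol per the labels, was sequenced from 3 control and 3 LPS livers. Per the labels, the authors' processing named bcl2fastq 2.0, HISAT2, StringTie, DESeq2, limma and the mouse genome build mm10, without saying which tool made the table. The authors deposited raw counts per gene, whole numbers with no normalization, in 1 table per library with a symbol, an Entrez gene identifier and a count. The counting tool, the gene annotation, the strand setting and the treatment of reads that map to several places were not given in the sources used here. Each table held 22488 genes in fields of 8 characters, so longer symbols and identifiers were shortened. Genes were therefore named from the mouse reference annotation (GRCm38.p6): 20722 by their Entrez identifier, carrying 98.99% of all counts, 855 by a complete symbol, and 546 by their symbol as deposited. A further 248 kept a shortened symbol and 117 had an identifier that the reference lacks. In 26 cases a symbol had been turned into a date, and 81 names stood on several lines. Counts of 6306 genes were 0 in all 6 libraries. No value column was left unused.

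Total counts per library ran from 11488525 to 20282004. Every library of a group differed from the others of that group by more than counting error (chi-square over degrees of freedom from 12.4 to 33.8), so none was the same library sequenced again, while separate libraries of the same liver are not excluded by this. The sample titles number the libraries of both groups as repeat experiments 1 to 3, and whether a control and an LPS library of the same number belong together is not stated. After subtracting group means, libraries of the same number correlated at -7.448e-04, 0.104 and 0.0352, and those of different numbers at -0.121 to 0.0741. The number was therefore not used in the model, and a fit with it as a block is an alternative. Nothing beyond the labels says that the libraries came from separate mice, and p values measure only the spread between these 6 samples. Intervals and floors given for counts cover counting error only.

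Genes were compared between LPS and control in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr (minimum count 10, minimum total 15, in at least 3 samples), and the quasi-likelihood F test, 2-sided. P values were adjusted by Benjamini-Hochberg over all 12078 genes tested, with a threshold of 0.05. The common dispersion corresponded to a biological coefficient of variation of 16.4%. A gene rose or fell where its adjusted p passed the threshold. Standard errors were taken from the log2 fold change and its F statistic. For a gene at 0 in a whole group, the fold was computed against 3 counts over the group. Values from fits with a library left out are those of the model, without this floor.

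Before the data were examined, 24 gene lists, the marker and quality lists, the tests, most alternative settings and the rule for named genes were fixed. The rule takes the 10 genes with the largest rise and the 10 with the largest fall among changed genes whose groups do not overlap and whose higher mean is at least 10 CPM. It also takes, in each list, the 3 members with the smallest adjusted p and the most abundant member, the changed members of the lists of PPAR receptors and of lipid droplet proteins, and a set of genes fixed by name that holds Ppara, Pparg, Ppard, Plin2, Cd36, Cpt1a, Pnpla2, Fasn and Dgat2. Some genes that the rule takes are not reported here, and counts of lists include them. Any other gene in the text was named after its values were seen. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, 2-sided, with adjustment over the 24 gene lists and over the 13 testable marker lists separately. Estimated correlations and fry were run beside it. Members were also counted with p values adjusted over the list alone. Spearman correlations between libraries and principal components used the log2 CPM values.

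The method was tested on simulated data, in which 200 genes were changed on the control means and dispersions of these libraries. Of 11601 genes tested, edgeR recovered 26.9% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 92.4% of those changed 4-fold, and 8.76% of its calls were false. DESeq2 recovered 34.3%, 70.1% and 90.9%. Since 200 genes changed there and 62.3% of tested genes in the data, a given adjusted p stood for a smaller raw p in the simulation. These shares therefore do not measure recovery or false calls in the data. A simulated 1.5-fold fall of the fatty acid oxidation list was called with the preset and the estimated correlation, with 0 of the other 23 lists called. In that simulation genes were drawn independently and genes outside the list were unchanged. In the data the list's estimated correlation was 0.318 and 62.3% of tested genes changed. The simulation therefore does not show how the list test behaves on these data.

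The alternative settings fixed then were the replicate block, leaving out each library in turn, DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts, a 2-fold minimum, estimated correlations and fry. Scaling by library totals or by the upper quartile, an offset per library for GC content and gene length, and the size factors and filter alternatives for the marker lists were added after seeing the data. Alternatives planned for normalized values did not apply, since the values were counts. GC content and length came from GENCODE M21 transcripts and were found for 12051 of the tested genes. Nuclear copies of mitochondrial genes were searched with BLAST 2.17.0 at 99% identity or more. Bootstrap intervals for differences of medians used 10000 draws over genes. Tables were handled in Python 3.11.15 with pandas 2.3.3 and plots were drawn with matplotlib 3.10.9.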

Results

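RNA from whole livers of male C57BL/6 mice was sequenced, 1 library per liver label. All mice were fasted for 16 h. The control group (n = 3) received 200 µl of HBSS, a balanced salt buffer, into the abdominal cavity, and the LPS group (n = 3) received lipopolysaccharide, the endotoxin of Gram-negative bacteria, at 6 mg/kg by the same route. Another label field of the control samples gives no treatment, so whether the differences below leave out an effect of injection is open. The time from injection to sampling was not given in the sources used here. The control libraries held 12577993, 20282004 and 15040698 counted reads in replicates 1, 2 and 3, and the LPS libraries held 11488525, 14191989 and 15437785. Between 13756 and 14402 genes had at least 1 count in a library. Values are counts scaled to a common library size (CPM), as mean ± SD with n = 3 per group, and log2 fold changes are LPS minus control with their standard error (SE). Adjusted p values for genes come from edgeR and those for gene lists from camera. Positions refer to the mouse assembly GRCm38 (mm10).

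The series asks whether LPS lowers signalling through the peroxisome proliferator-activated receptors (PPARs) and the storage of lipid droplets in the liver. LPS and control livers differed in most of the genes that passed the filter on low counts. Without the filter, 7787 of 16182 genes passed the threshold. Most tested members of the acute phase, cytokine, interferon and neutrophil lists rose, while most of those of fatty acid oxidation, bile acid handling, drug metabolism and Kupffer cells fell. With an estimated correlation between genes, 0 lists passed the threshold. That setting also ended the call of cytokines and chemokines, whose estimated correlation was -0.021, below the preset value. With an estimated correlation camera also takes its degrees of freedom from the 6 libraries, and with the preset one from the number of genes. The lost calls therefore cannot be put down to correlation between genes alone, and the contributions were not tested apart. Saa3, a serum amyloid A protein of the acute phase (chromosome 7, 46711998 to 46719615), went from 4.19 ± 0.422 to 5988 ± 468 CPM, and Cyp4a14, a fatty acid hydroxylase and PPAR-alpha target (chromosome 4, 115486200 to 115496158), went from 14548 ± 2218 to 47.9 ± 11.7 CPM. Of 12078 genes tested, 3781 were higher and 3747 lower in LPS livers at the threshold, and 1937 of the former and 2192 of the latter changed at least 2-fold. The LPS and control values did not overlap in 8142 tested genes (67.4%), where chance gives 10%. Spearman correlations over tested genes were 0.982 to 0.989 within groups and 0.835 to 0.844 between groups, and the first principal component held 84.7% of the variance.

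Among the genes with the largest rises were secreted proteins of the acute phase response and of neutrophil biology. Lcn2, an iron-siderophore binding protein (chromosome 2, 32384637 to 32387739), had a log2 fold change of 9.96 (SE 0.25, adjusted p = 7.408e-12), and Saa3 had 10.48 (SE 0.21, adjusted p = 1.016e-12). Csf3, the granulocyte colony-stimulating factor (chromosome 11, 98700183 to 98703631), had no count in any control library and 24.8 ± 1.83 CPM in LPS livers, at least 404-fold higher against a floor of 3 counts over the group. On the same floor C2cd4a, a nuclear factor induced by inflammatory signals in endothelial cells, was at least 513-fold higher, and Reg3b, a secreted C-type lectin, at least 252-fold higher. The LPS values of Reg3b were spread, with 6.31, 13.3 and 25.2 CPM in LPS replicates 1, 2 and 3. A2m (11.06), Crybb3 (9.55), Saa2 (9.14) and Gm10309 (9.34) completed this group together with Sult1e1, the oestrogen sulfotransferase. The 4 control counts of Gm10309 were all in control replicate 2. Without that library its control group had no count, and the 12.63 of that fit is a model value, not a measured fold. Crybb3 ran from 8.86 without control replicate 2 to 10.70 without control replicate 3. Sult1e1 had 2 control counts, both in control replicate 1, with a ratio of 1003 (95% counting interval 277 to 8287) and a log2 fold change of 9.68. Without that library its control group had no count, so the 12.27 of that fit is likewise not a measured fold. Among the largest falls were enzymes of lipid and bile acid metabolism. Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6265612 to 6275632), went from 147 ± 94.8 to 0.913 ± 0.801 CPM (log2 fold change -7.27, SE 0.52). Nr0b2, the bile acid-induced repressor of Cyp7a1, fell with it (-5.80), as did Klb, the co-receptor for the fibroblast growth factor that represses Cyp7a1 (-5.43). The others were Cyp4a14 (-8.24), Cyp4a10 (-5.71), the acyl-CoA synthetase Acss3 (-6.42), the phospho-lyase Etnppl (-5.81), Smad9 (-6.04), Tmem25 (-6.29) and Lrit1 (-5.95). Saa3, Csf3, Cyp4a14, Acss3, Etnppl, Tmem25 and Lrit1 overlap other genes, no position was found for Gm10309, and how reads shared by overlapping genes or by near-identical family members (Saa1 and Saa2, the Cyp4a genes) were counted was not given in the sources used here. The value of Acss3 rests on 5 LPS counts, all in LPS replicate 2. The fit gave -10.41 without that library, where the LPS group had no count, so this is a model value and not a measured fold. With a library left out Cyp7a1 ran from -6.60 (control replicate 1) to -8.27 (LPS replicate 2), Smad9 from -5.58 (LPS replicate 1) to -6.92 (LPS replicate 3) and Lrit1 from -5.65 (LPS replicate 2) to -6.61 (LPS replicate 3).

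Most genes of the inflammatory lists rose. Of 33 tested acute phase genes 30 rose and 3 fell, with a median log2 fold change of 3.18 (adjusted p = 6.291e-12, and adjusted p = 0.208 with an estimated correlation). Lcn2 reached 10797 ± 1291 CPM, and the metalloreductase Steap4 had a log2 fold change of 6.83 (SE 0.18). The 3 that fell were Crp, Ttr and Alb, 3 plasma proteins made by hepatocytes, of which Crp (-0.76) and Ttr (-0.50) were singled out after their values were seen. Of the list 1 fell without LPS replicate 2. The call of Ttr ended without control replicate 1 (-0.46) and without LPS replicate 2 (-0.39). Alb went from 79341 ± 8493 to 54469 ± 10899 CPM (-0.54, SE 0.18, adjusted p = 0.0201), a call that ended without control replicate 2 (-0.49) and without LPS replicate 2 (-0.52). Of 23 tested cytokines and chemokines 18 rose and 1 fell, with a median of 4.38, which did not move when the 2 genes at 0 in a group were set to their bounds (adjusted p = 1.955e-06, and adjusted p = 0.123 with an estimated correlation). Cxcl9, an interferon-induced chemokine for T cells, went from 4.90 ± 1.07 to 1732 ± 67.8 CPM, and the neutrophil chemokine Cxcl1 had a log2 fold change of 7.59 (SE 0.23). The faller was Ccl6 (-1.93), named after its value was seen, and 2 fell without control replicate 1, without LPS replicate 3 or without a filter on low counts. Of 29 tested genes of endotoxin sensing and NF-kB feedback 25 rose and 0 fell, with a median of 1.67 (adjusted p = 1.447e-08, and adjusted p = 0.208 with an estimated correlation), and 23 rose and 1 fell without LPS replicate 1. Cd14, the LPS co-receptor, went from 5.13 ± 1.49 to 1261 ± 210 CPM, and the feedback inhibitors Socs1 (7.50) and Tnfaip3 (4.79) rose too. Adjusted over the list alone, the counts of these 3 lists were the same. Neutrophil markers moved with them, with a median of 5.24.

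Of 39 tested interferon response genes 38 rose and 0 fell, with a median of 3.15 (adjusted p = 1.020e-14, and adjusted p = 0.282 with an estimated correlation), and 39 rose when adjusted over the list alone. The guanylate-binding protein Gbp2 went from 3.98 ± 0.547 to 784 ± 119 CPM, Gbp3 had a log2 fold change of 5.27 (SE 0.18) and the nucleic acid sensor Zbp1 one of 4.67 (SE 0.19). Of 23 genes of antigen presentation and the immunoproteasome 15 rose and 1 fell, also when adjusted over the list alone, with a median of 1.28 (adjusted p = 1.844e-04, and adjusted p = 0.282 with an estimated correlation). The immunoproteasome subunits Psmb10 (2.86) and Psmb8 (2.53) and the class I gene H2-K1 (1.00) rose, and the class II gene H2-Eb1, named after its value was seen, fell (-0.64, SE 0.25, adjusted p = 0.0341). The call of H2-Eb1 ended without control replicate 2 (-0.43), control replicate 3 (-0.70) or LPS replicate 1 (-0.49), which left 0 fallers. Fallers numbered 2 with the replicate block, with the offset for GC content and length or without LPS replicate 3, and 3 by library totals or without a filter. The T and NK cell and the monocyte markers had medians of 1.03 and 1.39 in the same libraries.

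Nearly all tested genes of the fixed list of fatty acid oxidation and PPAR-alpha targets fell, a list that does not hold every PPAR-alpha target. Of 45 tested, 41 fell and 2 rose, also when adjusted over the list alone, with a median of -1.44 (adjusted p = 4.627e-11, and adjusted p = 0.282 with an estimated correlation). Besides Cyp4a14 and Cyp4a10 (5739 ± 595 to 110 ± 47.4 CPM), Acsl1, which activates long-chain fatty acids, went from 2719 ± 288 to 235 ± 31.1 CPM (-3.53, SE 0.16), and the fatty acid transporter Slc27a1 fell (-3.67, SE 0.16). Cpt1a, which admits fatty acids to mitochondria, fell by less (708 ± 49.5 to 468 ± 74.9 CPM, -0.60, SE 0.14, adjusted p = 0.00222). The 2 members that rose, both named after their values were seen, were Pdk4, a kinase that restrains pyruvate oxidation (60.4 ± 44.8 to 1106 ± 183 CPM, 4.19, SE 0.46, and 4.84 without control replicate 3), and the mitochondrial carrier Ucp2 (0.80, SE 0.17). Of 7 ketogenesis genes 4 fell and 2 rose, also when adjusted over the list alone, with a median of -1.99 (adjusted p = 0.123). Bdh1, which interconverts ketone bodies (-3.47, SE 0.14, adjusted p = 2.091e-10), and Acat1 (-2.23) fell. The 2 that rose, the transporters Slc16a6 (2.81) and Slc16a1 (1.15), carry ketone bodies and other monocarboxylates across membranes and were named after their values were seen. Hepatocyte markers, which went both ways, had a median of -0.64 in these libraries. That median does not measure the hepatocyte share.

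PPAR receptors and coactivators went both ways. Of 16 PPAR receptors and coactivators 8 fell and 3 rose, also when adjusted over the list alone, with a median of -0.31 (adjusted p = 0.240). Ppara (chromosome 15, 85734910 to 85806851) went from 86.3 ± 7.80 to 112 ± 16.8 CPM (0.37, SE 0.14, adjusted p = 0.0276). Pparg fell from 5.98 ± 0.439 to 2.98 ± 0.864 CPM (-1.01, SE 0.29, adjusted p = 0.00785), and Ppard had a log2 fold change of -0.29 (SE 0.24, adjusted p = 0.299). The coactivator Ppargc1a fell (22.9 ± 8.70 to 6.02 ± 1.04 CPM, -1.94, SE 0.26), as did the receptors of oxysterols, Nr1h3 (-1.28), and of bile acids, Nr1h4 (-1.33), and the corepressor Ncor1 (-0.71). The retinoid partners Rxrg (-1.02), Rxrb (-0.51) and Rxra (-0.33, SE 0.13, adjusted p = 0.0456) fell, and the coactivators Ncoa2 (1.40) and Lpin1 (1.34) rose. The call of Ppara ended without control replicate 2 (0.35), control replicate 3 (0.29) or LPS replicate 3 (0.25), and with library totals as the only scaling (0.30). The call of Rxra ended without control replicate 1 (-0.29), control replicate 3 (-0.35), LPS replicate 1 (-0.24) or LPS replicate 2 (-0.38), and an offset for GC content and gene length ended those of Rxra (-0.13) and Rxrb (-0.27).

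Lipid droplet genes went both ways. Of 25 tested genes of lipid droplet proteins and lipolysis 15 fell and 5 rose, with a median of -0.92 (adjusted p = 0.0348, and adjusted p = 0.359 with an estimated correlation), and adjusted over the list alone 15 fell and 6 rose. Plin2, the main coat protein of hepatocyte droplets (chromosome 4, 86626910 to 86670217), rose from 1509 ± 269 to 5323 ± 89.4 CPM (1.82, SE 0.16, adjusted p = 3.043e-07). Hilpda, an inhibitor of the lipase Pnpla2, rose from 4.68 ± 1.73 to 41.3 ± 8.26 CPM (3.13, SE 0.24), and Pnpla2 itself rose (0.76, SE 0.18, adjusted p = 0.00191). The droplet fusion protein Cidec (1.34) and Rab18 (0.68) were the other risers. Lipa, the lysosomal acid lipase, went from 307 ± 43.9 to 43.2 ± 4.19 CPM (-2.83, SE 0.15), and Mgll, which cleaves monoglycerides, fell (-2.81, SE 0.17). The droplet proteins Hsd17b11 (-2.79), Hsd17b13 (-1.27), Plin5 (-1.32), Plin3 (-0.71), Cideb (-1.57), Ldah (-1.44) and Aup1 (-1.04) fell, as did Fitm1 (-1.60), Fitm2 (-1.28) and Bscl2 (-0.92), which act in droplet formation. The carboxylesterases Ces1f (-2.24), Ces1d (-1.35) and Ces3a (-0.57) fell as well. The call of this list ended without control replicate 3 (adjusted p = 0.0735) and without LPS replicate 2 (adjusted p = 0.0619), and RNA levels do not measure the droplets themselves. In the same libraries, hepatocyte markers had a median of -0.64.

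**Figure D1:**
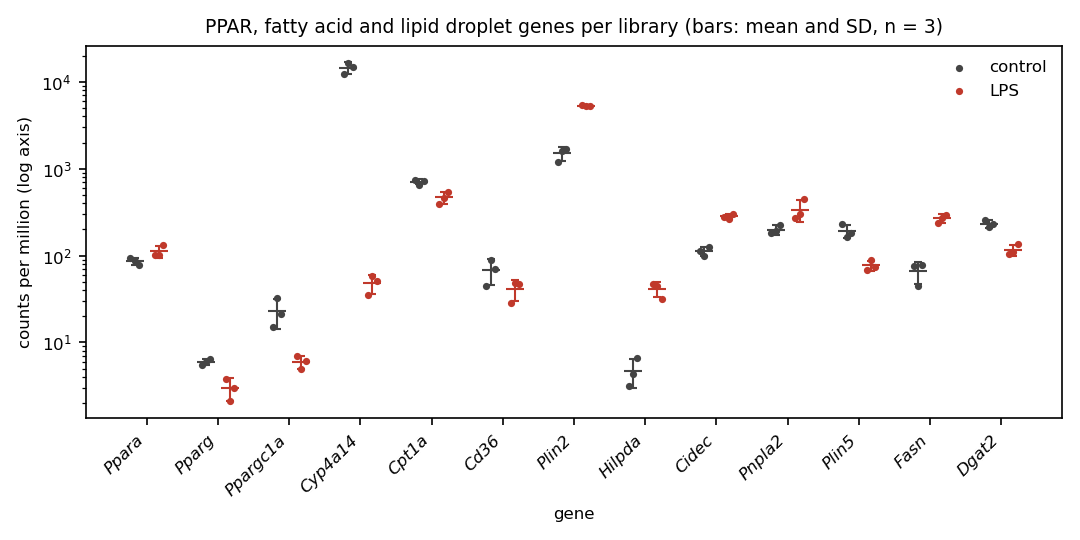
CPM on a log axis for 13 genes of PPAR signalling and lipid handling in each control (grey) and LPS (red) library, with mean and SD (n = 3 per group). Cyp4a14 and Ppargc1a were lower and Plin2, Hilpda and Fasn higher in LPS livers, while Ppara differed by a log2 fold change of 0.37.

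Triglyceride and fatty acid synthesis genes also split. Of 13 triglyceride synthesis genes 7 fell (8 when adjusted over the list alone) and 3 rose, with a median of -0.72 (adjusted p = 0.123). Lpin2, a phosphatidate phosphatase, went from 659 ± 36.0 to 107 ± 12.4 CPM (-2.63, SE 0.14), Gpat4 (-1.11) and Dgat2, which makes triglyceride in its last step (234 ± 23.4 to 117 ± 16.7 CPM, SE 0.14), fell. Lpin1 rose, as did Lpin3 (1.71) and Dgat1 (0.46), both named after their values were seen. Of 17 genes of de novo lipogenesis 9 fell and 3 rose, also when adjusted over the list alone, with a median of -0.51 (adjusted p = 0.167). Fads2 (-3.29) and Acss2 (-3.00) fell, whereas Fasn, the fatty acid synthase, rose from 66.3 ± 19.0 to 269 ± 29.5 CPM (2.02, SE 0.19) and the lipogenic regulator Thrsp rose (4.41, SE 0.27). The third riser, the regulator Srebf1 (0.66), was named after its value was seen. Scd1, the most abundant of the list, had a log2 fold change of 0.40 (SE 0.25, adjusted p = 0.186), which passed the threshold without control replicate 3 (0.69) and with the replicate block (0.42). Of 32 genes of fatty acid uptake and lipoproteins 20 fell (21 when adjusted over the list alone) and 5 rose, with a median of -0.76 (adjusted p = 0.00432, and adjusted p = 0.309 with an estimated correlation). Apoe went from 20045 ± 1748 to 11812 ± 1294 CPM (-0.76, SE 0.15), the sterol exporter Abcg8 fell (-2.05), and the fatty acid receptor Cd36 fell (-0.72, SE 0.23, adjusted p = 0.0161). Abca1, a cholesterol exporter (2.42), and the fatty acid carrier Fabp4 (2.81) rose, together with Fabp5 (2.42), the lipase inhibitor Angptl4 (0.99) and Apoa5 (0.65), the last 3 named after their values were seen. The call of Cd36 ended without control replicate 2 (-0.50) and without LPS replicate 1 (-0.53), and Apoa5 stood at 0.39 without LPS replicate 3. Beside the median of -0.76 for uptake and lipoproteins, hepatocyte markers had a median of -0.64, and share Apoa1 and Apob with that list.

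Most genes of bile acid handling, drug metabolism and amino acid catabolism fell. Of 21 genes of bile acid synthesis and transport 17 fell and 1 rose, also when adjusted over the list alone, with a median of -1.88 (adjusted p = 1.156e-05, and adjusted p = 0.237 with an estimated correlation). The uptake carrier Slco1b2 went from 997 ± 98.3 to 40.8 ± 5.58 CPM (-4.61, SE 0.16), and the canalicular exporters Abcb4 (-3.81) and Abcc2 (-3.80) fell. The riser was Cyp2c70, which makes muricholic acids (3.86, SE 0.16), named after its value was seen, and 2 rose without control replicate 1. Of 42 cytochrome P450 and drug metabolism genes 36 fell (37 when adjusted over the list alone) and 3 rose, with a median of -1.38 (adjusted p = 4.827e-09, and adjusted p = 0.282 with an estimated correlation). Aox3 (-3.76), Cyp3a25 (-3.51), Fmo1 (-3.02) and the most abundant member, Cyp2e1 (7421 ± 566 to 3197 ± 155 CPM, -1.22), fell. Cyp2a5 (1.10), Cyp2d40 (0.76) and Cyp1a2 (0.45), named after their values were seen, rose, and the call of Cyp1a2 ended without control replicate 1 or LPS replicate 1 (0.39 in both). Of 26 genes of the urea cycle and amino acid catabolism 18 fell and 4 rose, also when adjusted over the list alone, with a median of -1.14 (adjusted p = 0.00131, and adjusted p = 0.440 with an estimated correlation). Cps1, the entry enzyme of the urea cycle, went from 4860 ± 1403 to 390 ± 94.9 CPM (-3.64, SE 0.23) and Cth, of cysteine synthesis, fell (-4.60). The 4 risers, named after their values were seen, were Sdsl (3.03), Sds (1.13), Arg1 (0.86) and Glul (0.62). The call of Glul ended without control replicate 1 (0.34), LPS replicate 2 (0.56) or LPS replicate 3 (0.53), with the offset for GC content and length (0.53) and with DESeq2 (0.61), which also ended the call of Sds and left 2 risers of this list. Without LPS replicate 3 Sds stood at 0.60. Hepatocyte markers, of which 12 of 16 fell, had a median of -0.64 in the same libraries, and share Cyp2e1, Cyp3a11 and Cps1 with these lists.

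Most genes of the respiratory chain, and most of complement and coagulation, fell by smaller amounts. Of 45 nuclear genes of oxidative phosphorylation 31 fell (32 when adjusted over the list alone) and 0 rose, with a median of -0.53 (adjusted p = 1.558e-05, and adjusted p = 0.377 with an estimated correlation). Ndufs7 (-1.60), Ndufb5 (-1.20) and Atp5o (-1.18) had the smallest adjusted p values. Of 13 mitochondrially encoded transcripts 8 fell and 0 rose, also when adjusted over the list alone, with a median of -0.69 (adjusted p = 0.0257, and adjusted p = 0.485 with an estimated correlation), among them mt-Nd2 (6668 ± 675 to 3397 ± 300 CPM, -0.97, SE 0.15). Of 40 complement and coagulation genes 22 fell (23 when adjusted over the list alone) and 5 rose, with a median of -0.53 (adjusted p = 0.00233, and adjusted p = 0.411 with an estimated correlation). Klkb1 (-3.61) and Serpind1 (-3.00), of the contact and thrombin systems, fell. C3, the most abundant member, had a log2 fold change of 0.19 (SE 0.16, adjusted p = 0.331). Among the risers, and named after their values were seen, were F3 (1.05), C2 (0.63), F11 (0.61) and Serping1 (0.53), and the call of F3 ended without control replicate 1 (0.87), control replicate 2 (1.02) or LPS replicate 1 (0.89). Hepatocyte markers had a median of -0.64 beside these lists, and share F2 with the complement and coagulation list.

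Genes of protein folding went both ways. Of 29 genes of the unfolded protein response and chaperones 19 rose and 8 fell, also when adjusted over the list alone, with a median of 1.32 (adjusted p = 0.00768, and adjusted p = 0.359 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, went from 882 ± 175 to 6625 ± 1368 CPM (2.91, SE 0.20), and Creld2 (3.54) and Chac1 (6.29) rose. The cytosolic chaperone Hsph1 fell (-3.15), and so did the cytosolic heat shock genes Hspa1b (-4.74, and -5.35 without LPS replicate 2), Hspa1a (-2.46, and -3.45 without that library), Hspb1 (-2.05), Dnajb1 (-1.30) and Hspa8 (-1.24), these 5 named after their values were seen. The other fallers were the transcription factor Atf5 and the stress sensor Ern1. Of 21 liver transcription factors 12 fell (13 when adjusted over the list alone) and 3 rose, with a median of -0.52 (adjusted p = 0.0278, and adjusted p = 0.282 with an estimated correlation). Nr1i3, a xenobiotic receptor, went from 30.8 ± 6.93 to 1.57 ± 0.932 CPM (-4.27, SE 0.30, and -4.86 without LPS replicate 3) and Hnf4a fell (-0.52, SE 0.15), whereas Stat3 (2.03), Cebpd (2.02) and Cebpb (1.10, named after its value was seen), factors of the acute phase response, rose. The call of the transcription factor list ended without LPS replicate 2 (adjusted p = 0.0507). Beside this list, hepatocyte markers, which share Hnf4a with it, had a median of -0.64.

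**Figure D2:**
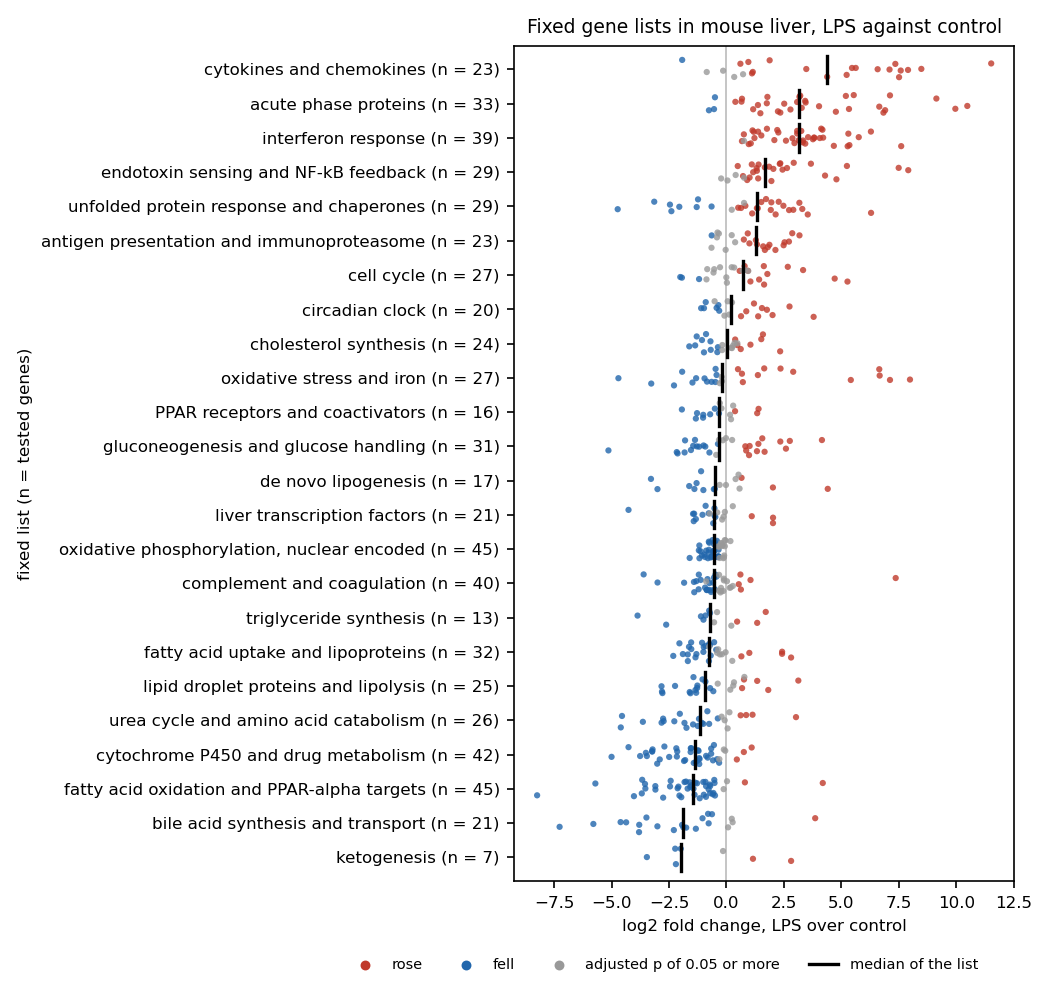
Log2 fold change (LPS minus control) of every tested member of the 24 fixed gene lists, with colour for genes that rose, fell or had an adjusted p of 0.05 or more, and a black bar at each list's median. Medians ran from 4.38 for cytokines and chemokines to -1.99 for ketogenesis.

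Markers of the cell types in the liver moved apart. Of 14 tested neutrophil markers 13 rose and 0 fell, with a median of 5.24 (adjusted p = 4.248e-07, and adjusted p = 0.342 with an estimated correlation). S100a9, a calcium-binding protein abundant in neutrophils, went from 1.22 ± 0.665 to 99.7 ± 10.2 CPM (6.28, SE 0.25), and the granule protein gene Ngp rose (8.05, SE 0.24). Of 13 Kupffer cell markers 12 fell and 1 rose, with a median of -2.21 (adjusted p = 8.560e-05, and adjusted p = 0.353 with an estimated correlation). Cd5l, a protein secreted by tissue macrophages, went from 80.4 ± 5.25 to 8.40 ± 0.976 CPM (-3.26, SE 0.14), and Csf1r (-3.15) and the iron exporter Slc40a1 (-4.70) fell. The exception was the scavenger receptor Marco (1.23, SE 0.27), named after its value was seen. Of 10 monocyte and recruited macrophage markers 7 rose and 1 fell, with a median of 1.39 (adjusted p = 0.0446, and adjusted p = 0.342 with an estimated correlation), with Chil3 (6.21) and Ly6c2 (4.54) higher and Lyz2 lower (-2.09). Of 11 T and NK cell markers 5 rose and 0 fell, with a median of 1.03 (adjusted p = 0.0446, and adjusted p = 0.342 with an estimated correlation), namely Gzmb (0.203 ± 0.273 to 5.34 ± 1.51 CPM), Gzma (2.79), Lck (1.95), Il2rb (1.03) and Prf1 (2.35), the last named after its value was seen. Of 9 B and plasma cell markers 4 fell and 0 rose, with a median of -1.09 (adjusted p = 0.0315, and adjusted p = 0.342 with an estimated correlation), among them Ighd (-3.26), Igkc (-0.98) and Ms4a1 (-1.63), the last named after its value was seen. Of 16 hepatocyte markers 12 fell, among them Cyp3a11 (-2.14), and 2 rose, Fga (3.21) and Tat (1.39) (adjusted p = 0.0275, and adjusted p = 0.562 with an estimated correlation). Adjusted over the list alone, the counts of these lists were the same. The call for T and NK cells ended whichever single library was left out (adjusted p from 0.0548 to 0.136), with 3 risers rather than 5 without LPS replicate 1. Of these genes Il2rb lost its call without control replicate 1 (0.80), control replicate 2 (0.90), LPS replicate 1 (0.99) or LPS replicate 2 (0.92), and Prf1 without control replicate 1 (1.90), control replicate 3 (1.81), LPS replicate 1 (2.21) or LPS replicate 3 (2.37). The 10 control counts of Prf1 were all in control replicate 2. Without that library its control group had no count, and the 6.79 of that fit is a model value, not a measured fold. The value of Lck was 2.55 without control replicate 2. Ly6c2 stood at 5.14 without control replicate 3. Gzmb had 0, 2 and 8 counts in control replicates 1, 2 and 3, and its log2 fold change ran from 4.19 to 6.28 over the alternative settings. The call for monocytes ended without control replicate 3 (adjusted p = 0.0810) or LPS replicate 1 (0.103), 2 (0.111) or 3 (0.0530), with 2 fallers rather than 1 without control replicate 3, LPS replicate 1 or LPS replicate 3, and that for B cells without control replicate 3 (0.0531), with 2 fallers rather than 4 without control replicate 2 or LPS replicate 3. Ms4a1 lost its call when any library except LPS replicate 2 was left out (-1.24 to -1.78), with the replicate block (-1.70), without a filter on low counts (-1.67) and with DESeq2 (-1.66).

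Of 18 liver sinusoidal endothelial markers 10 fell and 2 rose, with a median of -0.51 (adjusted p = 0.0539), which passed without LPS replicate 2 (adjusted p = 0.0104) and with the replicate block (adjusted p = 0.0286). Clec4g fell from 47.4 ± 1.91 to 5.37 ± 1.99 CPM and Gpr182 fell (-1.99), while Lyve1 (1.66) and Cdh5 (1.26, named after its value was seen) rose. Of 17 stellate cell and fibroblast markers 11 fell and 2 rose, with a median of -1.19 and a mean of -0.53 (adjusted p = 0.0619), which passed without LPS replicate 2 (adjusted p = 0.0369) and with the replicate block (adjusted p = 0.0393). Colec11 (-2.23) and Lrat, which forms retinyl esters (-1.61), fell, and Timp1, an inhibitor of matrix proteases that overlaps Syn1, rose (7.42, and 6.66 without control replicate 2 or 8.34 without control replicate 3), as did the collagen gene Col3a1 (0.69, named after its value was seen). Adjusted over the list alone, the counts of both lists were the same.

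Cholangiocyte, dendritic cell and erythroid markers each went both ways, with the same counts when adjusted over the list alone. Of 8 cholangiocyte markers 4 rose and 3 fell (adjusted p = 0.594), with a median of 0.79 and a mean of -0.03. Spp1 (2.44), Sox9 (2.30) and Epcam (0.94) were among the risers, and Krt23 (-3.73), Krt19 (-2.70) and Pkhd1 (-1.22) fell. Of 5 dendritic cell markers 2 rose, Bst2 (1.69) and Fscn1 (0.95), and 2 fell, Clec9a (-1.12) and Zbtb46 (-0.57), with a median of 0.66 (adjusted p = 0.617). Of 7 erythroid markers 3 rose, the haemoglobin genes Hba-a1 (0.72) and Hba-a2 (0.66) and the anion exchanger Slc4a1 (2.21), and Alas2 fell (-0.58), with a median of 0.24 (adjusted p = 0.454). Epcam, Krt19, Pkhd1, Zbtb46 and Alas2 were named after their values were seen. Several of these calls ended when 1 library was left out. Without control replicate 1 this held for Epcam (0.71), Pkhd1 (-1.06), Clec9a (-1.06) and Alas2 (-0.44), without control replicate 2 for Pkhd1 (-1.28) and Zbtb46 (-0.51), and without control replicate 3 for Epcam (0.84), Pkhd1 (-1.36), Clec9a (-1.12) and Zbtb46 (-0.57). Without LPS replicate 1 it held for Epcam (0.92), Pkhd1 (-1.22), Clec9a (-0.97), Zbtb46 (-0.62) and Alas2 (-0.43), without LPS replicate 2 for Epcam (0.82), Zbtb46 (-0.47) and Alas2 (-0.54), and without LPS replicate 3 for Pkhd1 (-0.77), Clec9a (-0.91), Zbtb46 (-0.61) and Slc4a1 (1.74). Pkhd1 kept its call without LPS replicate 2 (-1.89), where Krt19 stood at -3.60, Slc4a1 stood at 3.15 without control replicate 2, and Zbtb46 lost its call with the replicate block (-0.56), DESeq2 (-0.57) and the offset for GC content and length (-0.55).

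**Figure D3:**
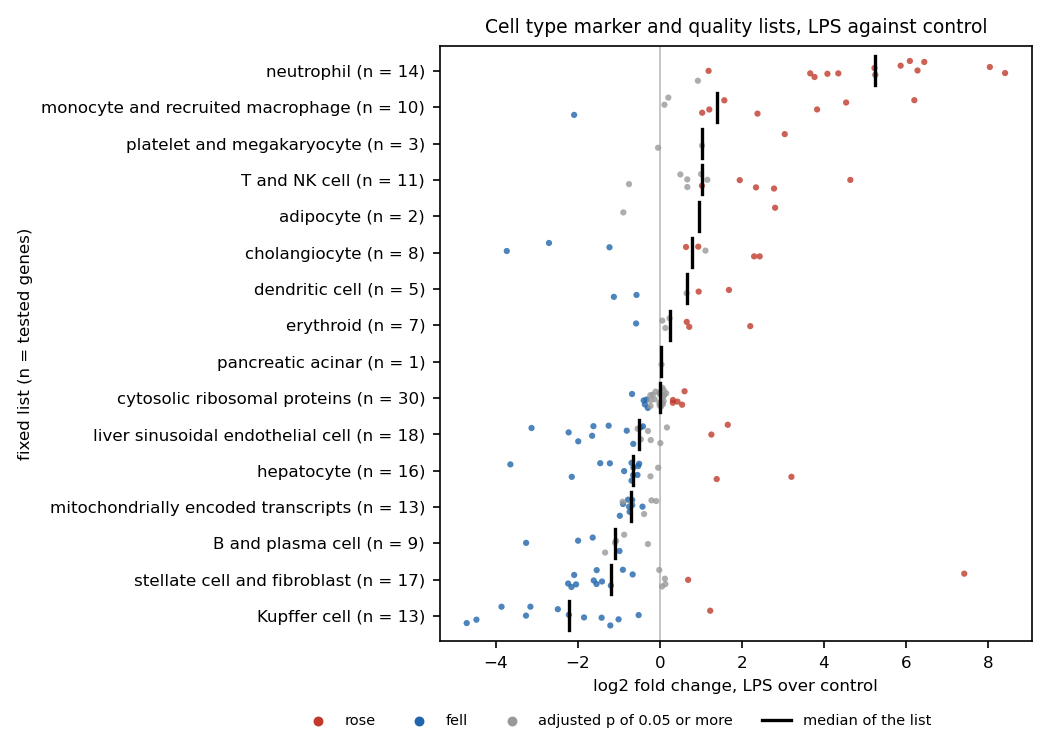
Log2 fold change (LPS minus control) of every tested member of the cell type and quality marker lists, with colour for genes that rose, fell or had an adjusted p of 0.05 or more, and a black bar at each list's median. The neutrophil median stood at 5.24 and the Kupffer cell median at -2.21.

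In all, 15 of 24 gene lists (6 up, 9 down) and 7 of 13 marker lists (3 up, 4 down) passed camera with its preset correlation, and 0 of either passed with an estimated correlation, where the lowest adjusted p was 0.123 for gene lists and 0.342 for marker lists. With fry, which asks whether a list's own genes move one way on balance, 22 gene lists and 11 marker lists passed, and 24 and 13 passed its test for change in either direction. Since 62.3% of all tested genes changed, passing the latter says little about a list, and the cytosolic ribosomal list passed it too. Control and LPS libraries carried separate ranges of library numbers, so any handling difference between the groups cannot be told apart from treatment.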

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

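Scaling by library totals or the upper quartile, the offset, and the size factor and filter settings for marker lists were chosen after seeing the data. Of the single genes followed, 233 to 244 kept their direction and side of the threshold under each setting on all 6 libraries, and 225 to 229 with a library left out. The 7528 changed genes became 7546 with the replicate block (7367 of them the same calls), 7525 with DESeq2 size factors, 7375 with DESeq2, where 1883 genes had no adjusted p, 7787 without a filter, 7420 by library totals, 7539 by the upper quartile and 7636 with the offset. Each left-out library gave 6898 to 7250, with fewer samples. A 2-fold minimum left 4129. Gene lists past the threshold numbered 15, 13 to 16 with a library left out and 0 with an estimated correlation; marker lists numbered 7, 4 to 7 with a library left out (4 without control replicate 3), 9 with the replicate block and 0 with an estimated correlation. Of the 45 tested PPAR-alpha target and 25 tested lipid droplet genes, 63 changed and 56 of these fell, and 54 to 57 fell with a library left out. Over the alternative settings 7 to 9 rose. Values that changed sign all belonged to results short of the threshold. Cela1 had a log2 fold change of -0.0021 without a filter, -0.034 by library totals and -0.019 with the offset, against 0.03, and -0.079 to 0.069 with a library left out. With the offset Hbb-bs stood at -0.026 and Itga2b at 0.11, and Itga2b ran from -0.19 to 0.12 with a library left out. The ribosomal list turned with the replicate block (adjusted p = 0.983), and with a library left out it gave 0.495 to 0.947, the cholesterol list 0.387 to 0.938 and the dendritic cell list 0.612 to 0.935. Without a filter the cell cycle list passed (adjusted p = 0.0328). Monocyte and T and NK cell markers failed without a filter (0.0573 and 0.171) and with the offset (0.0582 and 0.0827), and endothelial and stellate markers passed with the replicate block (0.0286 and 0.0393). Apart from fewer genes or samples, the cause was not tested. In the simulation, 26.9% of 1.5-fold changes were recovered with 3 libraries per group. This share does not carry over to the data, where far more genes changed.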

Other observations

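Beyond the groups described, several fixed lists held strong changes in both directions. Tests chosen only after the results were seen were those of a lower hepatocyte share, of more blood in the LPS livers and of 5 mitochondrial genes taken alone, and the offset for GC content and length and its count. Of 27 genes of oxidative stress and iron 12 rose and 12 fell, also when adjusted over the list alone. The median was -0.21 and the mean 0.91 (adjusted p = 0.805, direction up), with the metallothionein Mt1 (60.3 ± 20.8 to 6047 ± 127 CPM, 6.65), the zinc importer Slc39a14 (2.90) and the superoxide dismutase Sod2 (2.35) among the risers. Of 31 genes of gluconeogenesis and glucose handling 12 rose and 14 fell (15 when adjusted over the list alone), with a median of -0.33 (adjusted p = 0.605). Slc2a2, the glucose transporter of hepatocytes, went from 204 ± 13.98 to 5.74 ± 1.09 CPM (-5.14, SE 0.17), while the glycolytic genes Pfkfb3 (4.16) and Pkm (2.34) rose. Of 24 cholesterol synthesis genes 7 rose and 10 fell, also when adjusted over the list alone, with a median of 0.014 and a mean of -0.0098 (adjusted p = 0.706, direction down), and 4 rose without control replicate 2. Sqle rose (1.59, SE 0.28), and Sc5d (-1.36) and Insig2 (-0.69) fell.

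Of 20 circadian clock genes 9 rose and 6 fell, also when adjusted over the list alone, with a median of 0.18 (adjusted p = 0.226), and 3 fell without control replicate 2 or LPS replicate 1. Per1 (1.76), Nfil3 (1.20), Ciart (2.74) and Bhlhe40 (2.01) rose, and the hour of sampling was not given in the sources used here. Of 27 cell cycle genes 12 rose (11 when adjusted over the list alone) and 3 fell, with a median of 0.71 (adjusted p = 0.0595), which passed without control replicate 1 (0.0421), LPS replicate 1 (0.0468) or LPS replicate 3 (0.0374). The largest risers were growth arrest genes, Gadd45g (15.1 ± 5.34 to 580 ± 31.8 CPM, 5.27), Gadd45a (4.71) and Cdkn1a (3.33). The fallers, named after their values were seen, were Gadd45b (-1.94), E2f1 (-2.01) and Plk3 (-1.19), and the call of Plk3 ended without control replicate 3 (-0.64) and with DESeq2 (-1.20). Of 30 cytosolic ribosomal protein genes 5 rose and 5 fell (3 and 1 when adjusted over the list alone), with a median of 0.014 and a mean of -0.0026 (adjusted p = 0.991, direction down). Rplp2 (0.60), Rps27a (0.55, and 0.31 with the offset) and Rpl5 (-0.39) had the smallest adjusted p. The others, named after their values were seen, were Rps9, Rps12 and Rps24, which rose, and Rpl13a, Rps3, Rpl7 and Rps15, which fell. Fallers of this list numbered 1 without LPS replicate 2, 2 without control replicate 2 or LPS replicate 3, 3 without control replicate 1 or LPS replicate 1, and 8 with the offset. Risers numbered 2 without control replicate 3 and 3 without control replicate 1, without LPS replicate 1, without a filter, by library totals or with the offset. Rpl7 also lost its call with the replicate block (-0.29). Too few members for a list test were measured for platelets (Ppbp rose, 3.05, and 2.32 without control replicate 2 or 3.95 without control replicate 3, of 3 tested), adipocytes (Fabp4 rose, 2.81, of 2), the acinar pancreas (Cela1, 0.03, adjusted p = 0.894) and skeletal muscle (0 tested).

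The fall of fatty acid oxidation and PPAR-alpha target genes was weighed against a lower share of hepatocyte RNA and against sequence bias. The list's median lay below that of the hepatocyte markers by a difference of -0.79 (bootstrap 95% interval -1.30 to -0.27, over genes and not livers). Those markers went both ways under LPS, with 12 of 16 lower, such as Cps1 and Cyp3a11, and 2 higher, Fga and Tat. Their median therefore does not measure the hepatocyte share, and a lower share stays open. With the offset for GC content and length, 100% of the 41 members still fell, which argues against that bias. Control files carried header numbers from 2572 to 2574 and LPS files from 100 to 102, with 0 blocks of these numbers shared by both groups, so separate handling of the 2 groups cannot be told apart from treatment. An LPS effect on these genes within hepatocytes therefore remains a hypothesis.

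Most neutrophil markers rose while most Kupffer cell markers fell. A lower hepatocyte share alone would raise both, and the Kupffer median of -2.21 (bootstrap 95% interval -3.26 to -1.20) argues against it as the only cause. A lower share together with loss of Kupffer cells or lower expression per cell stays open. More blood of unchanged makeup in the LPS livers would raise erythroid markers alike, and their median lay below the neutrophil median by a difference of -5.004 (interval -6.05 to -3.34). Of 7 erythroid markers 3 rose and 1 fell. Whether LPS changed the makeup of the blood was not measured, so blood as a source of the neutrophil RNA stays open. The equal fall predicted for loss of Kupffer cells alone was not seen. The SD of the markers' changes was 1.68, 7.13 times the median standard error, and Marco rose. Cell loss alone would lower the markers equally only if no other cell type expressed them. That was not measured, and C6 (-0.51) is also in the complement list, so cell loss alone stays open. Loss of cells, changes per cell or both may explain the values, and separate handling of the 2 groups stays open here too.

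The mitochondrial genes mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l had far fewer counts than the other 7 in all 6 libraries, with at most 4.30% of the counts per kilobase of the lowest of the others, which argues against short length as the cause. Transcripts of near-identical nuclear copies covered at least 98.99% of 5 of them, in a stretch of chromosome 1 from 24611535 to 24616197, and at most 63.6% of a high gene, mt-Nd4, so reads shared with these copies are a candidate explanation for the 5. For mt-Atp8 the cover was 21.08%, but most of its 204 bp was not searched, because the transcripts leave a gap of 233 bp there (230 bp in the mitochondrial genome), and mt-Nd4 exceeded the 50% bound set beforehand for the others. The explanation therefore stays open for all 6 together. No biological explanation was tested, and the 6 genes' levels are not those of their transcripts if reads were shared.

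A hypothesis was tested that growth hormone signalling, which sets sex-biased expression in the liver, was lower under LPS, which would lower male-biased and raise female-biased genes. Of 22 male-biased genes 13 fell and 4 rose, with a median of -0.52 (adjusted p = 0.118, and adjusted p = 0.522 with an estimated correlation), which leaves the first part undecided. Of 23 female-biased genes listed, 13 were tested in these male livers. Of these 13, 8 fell and 1 rose, with a median of -2.47 (adjusted p = 0.0165, and adjusted p = 0.149 with an estimated correlation), against the predicted rise. Atp6v0d2, Cyp3a44, Prom1 and Cyp3a16 had low mean log2 CPM (-0.38, 0.35, 0.64 and 0.76). Among the 13, Cyp4a10 and Acot3 are also in the PPAR-alpha target list, and Cyp3a16 and Cyp17a1 are in the drug metabolism list. Most genes of those lists fell, though Acot3 did not (-0.12, adjusted p = 0.714). The fall of the female-biased list is therefore partly shared with theirs. The same holds for the male-biased list. Its fallers Cyp4a12a, Cyp2u1, Cyp2d9, Gstp1, Slco1a1, C6 and C8b are in the lists of PPAR-alpha targets, drug metabolism, bile acids or complement. Of 10 growth hormone targets 4 fell and 2 rose, with a median of -0.37 (adjusted p = 0.347). Socs2 (3.36) and Cish rose, and Igfals (-2.68) and the receptor gene Ghr (-1.16) were among those that fell, these 4 named after their values were seen.

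The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05, and every division but the real one mixes the groups. The real division gave 7528 changed genes, and the highest of the others gave 0 (1 of 10 as large). For PPAR-alpha target and lipid droplet genes that fell the values were 56 and 0 (1 of 10), for gene lists 15 and 16 (4 of 10 as large), and for marker lists 7 and 6 (1 of 10). The mixed divisions keep part of the LPS difference between their groups and put the rest into the spread within them. Their 0 changed genes and up to 16 gene lists therefore do not measure what chance gives.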
